A study of Homo sapiens with 9 samples.

How the data were processed

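The series profiled Huh-7 cells with stable shRNA against GFP, NDRG3 or HIF1A on Illumina expression arrays. Total RNA was column-purified, and 200 ng was amplified and labelled with biotin, per the labels' protocols. The scanner, the array software and the normalization tool are not given in the sources used here. Groups were taken from the sample titles, and all 9 arrays form groups of 1.

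The authors deposited a probe value table per platform and a gene-level table over all arrays, each holding intensity on a linear scale. Sorted probe values were near identical between the arrays of a platform (largest log2 deviation 0.0269 on the 6-array platform and 0.004 on the 3-array platform), so the deposited intensity values appear quantile normalized within each platform; this was read from the values, as no label states it. The lowest probe values were 58 and 104.7 and the medians 141.7 and 183.3, so background had not been subtracted and differences of dim genes are understated. Signal over background, not depth, sets the precision of an array. The probe tables held 29377 and 48803 probes. No table used here pairs probes with genes, so the gene-level table of 18153 genes became the main source in place of the probe tables planned. Of its genes, 12770 equalled 1 probe of the 6-array platform and 11960 of the 3-array platform (tolerance 0.0002 of the highest value, at least 0.02), and 199 of 300 others tried equalled the mean of 2 probes. The deposited table therefore averages probes for some genes, and the planned mean over all probes of a gene was not run. All columns belonged to samples of the series.

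Gene names were brought up to date through the synonyms of a RefSeq table (GRCh38.p14 assembly), used for names alone: 15058 were current, 2282 were renamed through 1 synonym and 813 were kept as filed. Probe positions were not used here.

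Values were analysed as log2(intensity + 32) without further normalization, and every difference is on that scale. A gene entered a comparison if it reached the 40th percentile of its platform's values (127.3 or 210.2) on at least 1 compared array. Single comparisons rest on 1 array each and carry no test: genes at least 2-fold apart were counted as a description. In the additive models time points stood in for replicates, so p-values measure the spread between times of 1 line each, not between cultures. The 24 h arrays lie on the second platform, so that spread also holds platform and probe effects. limma 3.58.1 (R 4.3.3; lmFit and eBayes, Benjamini-Hochberg adjusted p under 0.05) was fitted to the 5 shGFP arrays with a platform block and 1 hypoxia term, and to all 9 arrays with a mean per condition and time, 1 NDRG3 term and 1 HIF1A term. Each left 2 residual degrees of freedom (prior 5.07 and 3.77). The lone shHIF1A array was assumed to vary like the others. In the text "rose" and "fell" refer to limma calls, over all genes or over a list alone where so stated; other values are given as differences.

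Medians of 11 gene lists and of induced sets were placed as percentiles among 10000 random lists of the same size, matched on mean expression in 20 bins. Random lists draw genes independently and hold no variation between cultures. A list of co-regulated genes can therefore reach an extreme percentile through a small difference between cultures. A percentile describes a list on these arrays and is no test of hypoxia or of a knockdown. List members not in the table were HILPDA, FAM162A, CDK1, FDPS, HSD17B7 and HBA1. Differences were taken within a platform, apart from that between the shGFP normoxia arrays in the closing section, which crosses platforms. Induced sets and knockdown effects were taken from arrays they do not share; the shared-array correlation was set beside 100 simulations. The designs, gene lists and rule for named genes were fixed before the data were examined. The rule named NDRG3, HIF1A, EPAS1 and NDRG1 throughout. For hypoxia and for NDRG3 it took the 8 largest mean differences in each direction among genes past the test, filled where fewer passed by the smallest absolute difference over the 3 times among genes of 1 sign. For HIF1A it took the 8 largest differences in each direction, and from each list up to 4 measured members with the largest absolute difference; provisional names were left out. Genes it named in one comparison could be followed in others, and members called over a list alone were named where few, a choice made after the calls were seen. Other genes named were chosen after their values were seen and are marked so. A gene that the rule names is not reported here.

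The limma steps were tested on simulated data over the same genes with 200 genes changed: for NDRG3, 100% of genes changed by a log2 of 1 were recovered, for HIF1A 86%, and for hypoxia 98%. Of the unchanged genes, 19, 15 and 13 were called. The simulated spread followed the fitted model, so these shares can be optimistic. Alternatives covered the filter, centring, the pseudocount (8 and 128), the size threshold (1.5-fold and 3-fold), the probe tables, the moderation (trend and robust) and leaving out each time. Added after seeing the data were a second quantile normalization, genes equal to 1 probe, background subtraction (the 10th percentile, with a floor of 16) and a filter passed on each platform. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for names, correlations, resampling and plots.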

Results

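Gene expression was measured in Huh-7 cells, a human hepatoma line, that stably carried a lentiviral short hairpin RNA (shRNA) against NDRG3, against HIF1A (the alpha subunit of hypoxia-inducible factor 1) or against GFP as the control. Cells were kept in normoxia or in hypoxia (1% oxygen) for 6, 12 or 24 h. The 9 arrays formed 9 groups of 1 array each. A set of 6 arrays on one Illumina platform held shGFP cells in normoxia (1 array for the 6 h and 12 h series), shGFP cells after 6 h and 12 h of hypoxia, shNDRG3 cells after 6 h and 12 h of hypoxia, and shHIF1A cells after 12 h of hypoxia. The other 3 arrays, on a second platform, held shGFP cells in normoxia and after 24 h of hypoxia, and shNDRG3 cells after 24 h of hypoxia. No condition was replicated, so a difference at one time has no replicate check, and the number of arrays limits the precision. Median intensity per gene lay between 169 and 173 on the first platform and between 270 and 276 on the second, and every difference in the comparisons below was taken within a platform.

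The targeted genes were examined first. NDRG3 intensity was 268 in shNDRG3 cells at 6 h against 1278 in shGFP cells, 215 against 1456 at 12 h, and 233 against 1712 at 24 h, log2 differences of -2.13, -2.59 and -2.72. Over the 3 times NDRG3 fell by 2.48 (SE 0.13; limma, Benjamini-Hochberg adjusted p = 0.0318), lower at 3 of 3 times. The call ended with no filter, with the higher pseudocount, after background subtraction and without the 12 h arrays; over the alternatives in which the gene was tested the limma adjusted p ranged from 2.15e-15 without the 24 h arrays to 0.706 after background subtraction, with log2 differences from -3.55 to -2.13. HIF1A intensity was 231 in shHIF1A cells at 12 h against 897 in shGFP cells, a log2 difference of -1.82. NDRG3 in shHIF1A cells (1428) was close to its control level. HIF1A in shNDRG3 cells differed by -0.03 at 6 h, 0.24 at 12 h and -0.74 at 24 h.

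**Figure D1:**
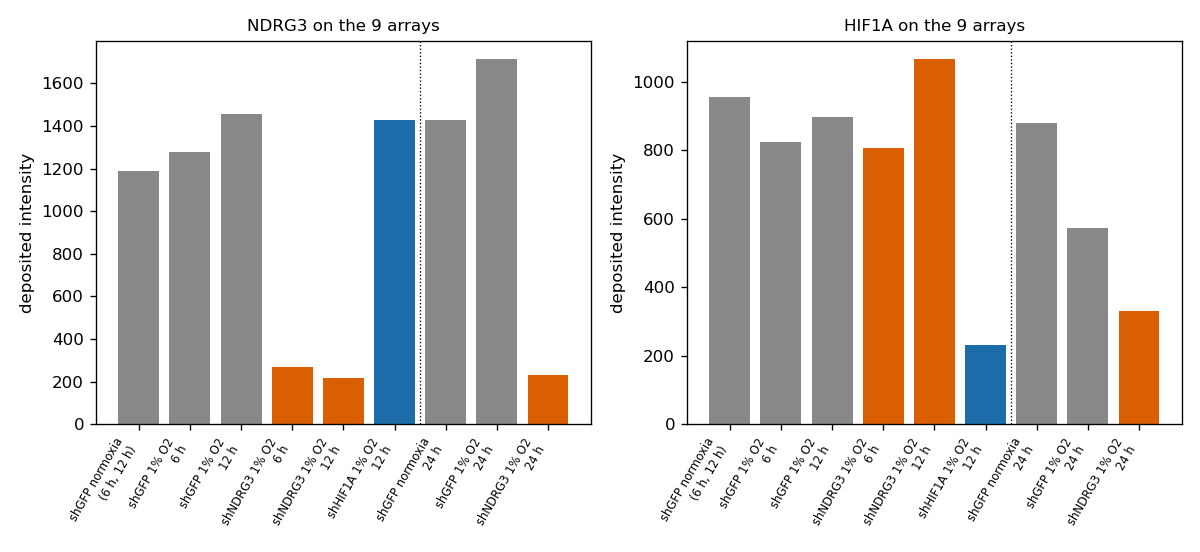
Deposited intensity (linear axis from 0) of NDRG3 and HIF1A, 1 bar per array, with shGFP in grey, shNDRG3 in orange and shHIF1A in blue; the dotted line parts the platforms, between which levels are not comparable. NDRG3 lay at 268, 215 and 233 on the shNDRG3 arrays, and HIF1A at 231 on the shHIF1A array.

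The first comparison asked how control cells responded to low oxygen. Genes of glucose uptake and glycolysis and other known hypoxia-inducible genes were strongly higher at every time. PFKFB4, which makes a regulator of glycolytic flux, rose by 3.91 (SE 0.41; limma, adjusted p = 0.0145), and the glycolytic enzyme gene ALDOC rose by 3.20. ANKRD37 rose by 3.86 (SE 0.23, limma adjusted p = 0.00252), the collagen cross-linking enzyme gene LOX by 3.80, the carbonic anhydrase gene CA9 by 3.33, the vasoactive peptide gene ADM by 3.10, and the growth factor binding protein gene IGFBP3 by 3.24. NDRG1, a relative of NDRG3, rose by 2.85 (SE 0.26, limma adjusted p = 0.0101), whereas the NDRG3 difference was 0.22 and did not pass (limma adjusted p = 0.398). EPAS1, which encodes HIF-2 alpha, differed by 0.59 and HIF1A by -0.34, and neither passed the test. The metallothionein gene MT1X rose by 3.38, and the heat shock genes HSPA1A and HSPA1B fell by 2.79 and fell by 2.19; these genes have near-identical relatives, so their probes may not separate them. GEMIN6, EVA1C, PDK4 (a kinase that restrains pyruvate dehydrogenase), EMP1 and TOR3A also fell, by log2 values from -1.25 to -1.03. RRS1, a ribosome assembly gene, differed by -1.67 and did not pass (limma adjusted p = 0.0879).

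In limma over the 5 shGFP arrays, 49 genes rose and 7 fell of 12774 tested, with 2480 at an unadjusted p under 0.05. With no filter limma called 3 genes, with the higher pseudocount 7, and after background subtraction 0, with 1953 at an unadjusted p under 0.05 there. Of 22 glycolysis and lactate genes tested, 7 rose, and 18 rose when adjusted over the list alone; SLC2A3, a glucose transporter gene, rose by 2.92 and HK2, a hexokinase gene, by 2.53. Of 34 other hypoxia-inducible genes, 18 rose, and 29 when adjusted over the list alone. At least 2-fold differences were seen for 102 genes higher and 6 lower at 6 h, 284 higher and 175 lower at 12 h, and 313 higher and 227 lower at 24 h. The balance at 12 h and 24 h depends on the threshold: at 1.5-fold it was 799 higher and 803 lower at 12 h, and 1044 higher and 1070 lower at 24 h (1166 and 1185 at 2-fold after background subtraction). Of the 102 genes higher at 6 h, 99 were also 2-fold higher at 12 h, where the same normoxia array served both times, and 57 at 24 h on separate arrays (2.5 for independent lists). The limma count was 949 without the 6 h array (479 rose and 470 fell, so the excess of risen genes was nearly gone), 94 without the 12 h array (82 and 12) and 90 without the 24 h arrays (85 and 5), each with 1 residual degree of freedom.

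Most stress response genes were higher in hypoxia. Of 24 genes of the integrated stress and unfolded protein response, 2 rose, and 15 rose and 3 fell (HSPA5, SDF2L1 and SLC7A11) when adjusted over the list alone. DDIT3, a stress-induced transcription factor gene, rose by 2.51 (SE 0.31, limma adjusted p = 0.0305). ATF3 differed by 0.19 at 6 h, 0.70 at 12 h and 2.81 at 24 h, and the amino acid synthesis gene ASNS by 0.57, 1.55 and 1.32. Of 20 ERK pathway output genes, SPRY1 rose by 1.67 and FOS by 1.62, and 6 rose and 2 fell (CCND1 and MYC) when adjusted over the list alone. None of 21 angiogenic and inflammatory secreted factors passed over all genes in limma; 3 rose (VEGFA, IL1A and PTGS2) and 1 fell (FGF2) when adjusted over the list alone. CXCL8, a neutrophil chemokine gene, differed by 0.04 at 6 h, 0.70 at 12 h and 2.69 at 24 h.

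In hypoxia cholesterol biosynthesis genes had medians of -0.12, -0.26 and -0.34 at 6, 12 and 24 h, the last at the 0.3 percentile of random lists; among genes equal to 1 probe the 24 h median was -0.29 over 13 members (3.1 percentile), inside the central 95%, as was the 12 h median (-0.26, 5.3 percentile). Proliferation genes had medians of -0.14, -0.29 and -0.18, the last being -0.48 (0.1 percentile) among genes equal to 1 probe; CDC20 was at -1.80 at 12 h. Oxidative phosphorylation genes had medians between -0.18 and -0.03, with ATP5MC1 at -1.54 at 12 h. Interferon-stimulated genes had medians between -0.24 and -0.10; the lowest, at 24 h (1.6 percentile), was -0.23 with the 60th percentile filter (11.3) and -0.11 among genes equal to 1 probe (32.5), both inside the central 95%. In limma none of the members of these 4 lists passed over all genes; adjusted over the list alone, CCNE2 rose and BUB1B fell among proliferation genes, and ISG20 rose and IFIT2 and MX1 fell among interferon-stimulated genes. Hepatocyte genes were near background on all 9 arrays: of 25 members in the table, 2 to 5 lay over the filter value on any one array, ALB intensity lay between 160 and 229, and APOA1 was at 345 on its highest array. The median member ranked between the 17.4 and 28.7 percentile of an array's values. These are low levels for genes typical of a hepatoma line, and neither the identity of the cultures nor the response of these probes was tested. Of 18 markers of other cell types, 4 to 7 lay over it, and their hypoxia medians were between -0.22 and -0.02.

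**Figure D2:**
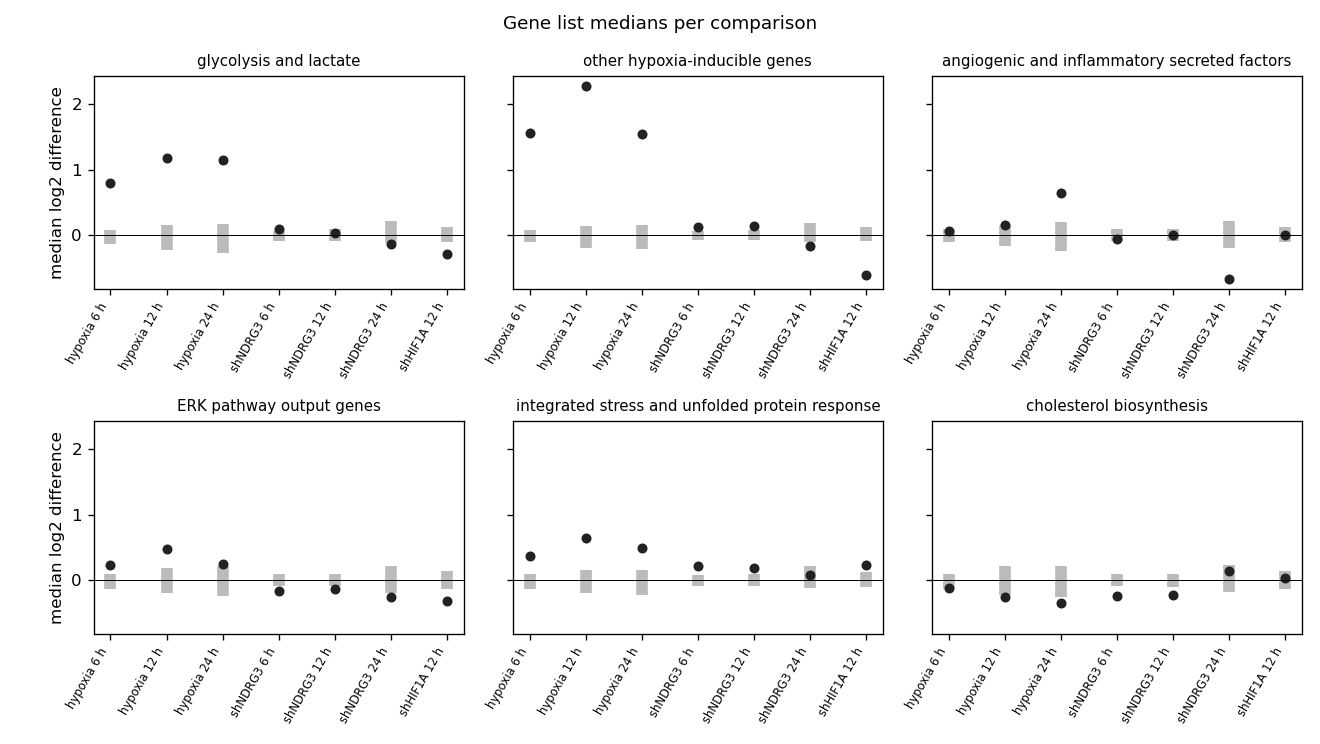
Median log2 difference of the measured genes of 6 lists (vertical axis) in each comparison (horizontal axis: hypoxia against normoxia in shGFP cells, then knockdown against shGFP cells in hypoxia). Points are list medians and grey bars span the central 95% of 10000 expression-matched random lists; the hypoxia-inducible list lay at 1.56, 2.28 and 1.54 in hypoxia and at -0.61 in shHIF1A cells.

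The second comparison asked which genes differed in hypoxia when NDRG3 was depleted. At 6 h and 12 h few did: 5 genes were at least 2-fold higher and 8 lower at 6 h (206 and 203 after background subtraction), and 7 higher and 12 lower at 12 h. TCIM was lower at each time (-2.04, -2.02 and -1.48), as were IFI27, an interferon-stimulated gene (-1.24, -1.17 and -0.82), and MFAP5, a microfibril gene (-0.78, -1.07 and -2.72). PI3, GCNT3, TNNC1 and EMP1 were also lower at each time. ATP5MC1, a subunit gene of the mitochondrial ATP synthase, was higher at each time (1.33, 1.85 and 1.76), as were GLO1, which makes a methylglyoxal-detoxifying enzyme (0.94, 1.21 and 1.21), and ITPK1 (1.09, 1.68 and 0.93). TMED5, CKB (brain-type creatine kinase), REEP1, CYFIP2 and FOXF2 were higher at each time too. All of these higher and lower genes differed in the same direction on the shHIF1A array at 12 h. That difference shares its shGFP array with the 12 h shNDRG3 difference that helped to pick them, so agreement is partly built in. On the shHIF1A array all but GCNT3 also lay beyond the shGFP normoxia and 6 h arrays in that direction. Those differences from shGFP cells were thus not limited to shNDRG3 cells. GCNT3 was at 1927 there, against 1743 and 1788. In limma over the 3 times, NDRG3 was the 1 gene of 13237 that passed, with 1129 at an unadjusted p under 0.05; TCIM and ATP5MC1 each had an adjusted p of 0.0724. Without the 24 h arrays limma called 318 genes higher and 328 lower; that fit had 1 residual degree of freedom and a prior of 26.27, against 3.77 with all arrays, so its calls lean on variance pooled across genes. Without the 12 h arrays limma called 0, with 559 at an unadjusted p under 0.05.

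Known hypoxia-inducible genes were not lower in shNDRG3 cells at 6 h and 12 h. The medians of the hypoxia-inducible list were 0.13 and 0.14, both at the 100 percentile of random lists, and those of the glycolysis list 0.10 and 0.04. Among genes equal to 1 probe the hypoxia-inducible median at 6 h was 0.08 (95.5 percentile) and so inside the central 95%. CA9 differed by 0.12 and -0.05, NDRG1 by 0 and -0.02, and HK2 by 0.56 and 0.50. EPAS1 was higher at 6 h and 12 h (0.81 and 0.74) and lower at 24 h (-1.22). ERK pathway output genes had medians of -0.16, -0.14 and -0.26 at 6, 12 and 24 h, at the 0, 0.3 and 0.4 percentile of random lists. The 24 h median was inside the central 95% with the 60th percentile filter (-0.14, 12.4 percentile). It was also inside among genes equal to 1 probe (-0.14, 11.5) and after background subtraction (-0.31, 3.5). CCND1, a G1 cyclin gene, was at -1.21, -1.30 and 0.01, whereas FOS was at 0.02, 0.87 and 1.07. Members above 0 were 3 of 19 at 6 h, 5 of 19 at 12 h and 8 of 20 at 24 h. When adjusted over the list alone 4 of 21 fell (ETV4, ETV5, PHLDA1 and EPHA2), and 0 passed over all genes in limma. Cholesterol biosynthesis genes had medians of -0.24 and -0.22 at 6 h and 12 h, both at the 0 percentile of random lists, and 0.14 at 24 h. Among genes equal to 1 probe the 6 h median was -0.09 (6.4 percentile). Random lists hold no co-regulation, so these percentiles do not set a knockdown effect apart from a difference between cultures. EBP, a sterol isomerase gene, was the 1 of 20 that fell when adjusted over the list alone. Stress response genes had medians of 0.21, 0.19 and 0.08, the 12 h value being 0.09 (93 percentile, inside the central 95%) among genes equal to 1 probe, and ATF3 alone of 24 rose when adjusted over the list alone. Interferon-stimulated genes had medians of -0.12, -0.13 and -0.20, but none kept its place outside the central 95% under every alternative: among genes equal to 1 probe the medians were -0.02 at 6 h (30.1 percentile) and -0.11 at 12 h (5.1), and with the 60th percentile filter 0 at 24 h (40.4). Secreted factors had medians of -0.05 and 0 at 6 h and 12 h, inside the central 95%, but -0.12 at 6 h among genes equal to 1 probe (2.2 percentile) and 0.18 at 12 h with the 60th percentile filter (99.4). Proliferation genes (0.01, 0.07 and 0.11), oxidative phosphorylation genes (-0.04, -0.01 and 0), hepatocyte genes (0.07, 0.03 and 0.10) and markers of other cell types (0.02, 0.14 and -0.24) had medians inside the central 95% of random lists.

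At 24 h the shNDRG3 array differed far more, with 298 genes at least 2-fold lower and 78 higher. Hypoxia-induced and secreted factor genes were among the lower ones: CA9 was at -3.07, the lactate transporter gene SLC16A3 at -3.37, CXCL8 at -2.94 (intensity 197 against 1728) and IL1A at -2.25. The 16 measured secreted factors had a median of -0.67 (0 percentile of random lists), with 5 at least 2-fold lower, among them CCL20 at -1.15. With no filter all 28 members in the table had a median of -0.09 (2.8 percentile), inside the central 95%. The filter itself depends on these arrays, with 15 of the 28 over it on the shGFP array and 10 on the shNDRG3 array, so the median of the 16 does not show that the list as a whole was lower. The glycolysis list was at -0.13 and the hypoxia-inducible list at -0.17. ALDOC (10710 against 12159), ANKRD37 (8280 against 9045) and PFKFB4 (8032 against 6918) had intensities near the control. The genes lowest at 24 h, named after their values were seen, had high control levels and included CRIP1 (402 against 7785), the calcium-binding protein gene S100A4 (1230 against 22319), the keratin gene KRT17 (797 against 13354) and TM4SF1 (712 against 11561). These lay below their normoxia levels too (8047, 24971, 7762 and 24102), and on the 6 h and 12 h shNDRG3 arrays S100A4 was at 46315 and 42326. Among 10949 genes over the filter on both platforms, 64 were at least 4-fold lower at 24 h and 5 at least 4-fold higher; the median difference of the 64 was -2.72 at 24 h, -0.02 at 6 h and -0.09 at 12 h. After background subtraction, an alternative that enlarges differences of dim genes, 1095 genes were at least 2-fold lower and 882 higher at 24 h. PPP1R14C and STK39 were the highest, at 2.72 and 2.28; STK39 was named after its value was seen. Time and platform cannot be told apart here, since 24 h was measured on a platform of its own.

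**Figure D3:**
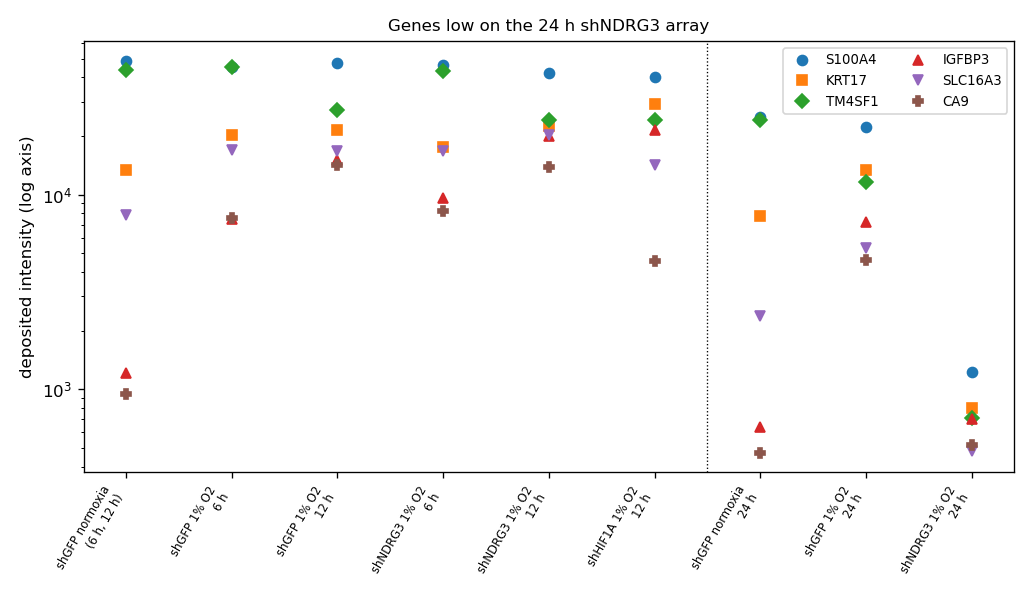
Deposited intensity (log axis) of 6 genes that were low on the 24 h shNDRG3 array, 1 point per gene and array; the dotted line parts the platforms, between which levels are not comparable. S100A4 was at 46315 and 42326 on the shNDRG3 arrays at 6 h and 12 h, and at 1230 at 24 h against 22319 in shGFP cells.

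The third comparison asked which genes differed in shHIF1A cells at 12 h of hypoxia. It rests on 1 array, and a different mix of cell populations on that array was not excluded, as given in the closing section. Known hypoxia-inducible genes were lower in shHIF1A cells: BNIP3, a mitophagy gene, was at 8012 against 28731 (-1.84), and the glycogen-targeting gene PPP1R3C (-1.79), ALDOC (-1.78), the sterol sensor gene INSIG2 (-1.88), CA9 (-1.64) and PFKFB4 (-1.46) were lower as well. The hypoxia-inducible list had a median of -0.61 and the glycolysis list -0.28, both at the 0 percentile of random lists. PPFIA4, ITPR1 (a calcium release channel gene) and BMP6 were lower by log2 differences of -2.05, -1.99 and -1.99. NDRG1 (-0.21) differed little, and LOX (11071 against 5764) and IGFBP3 (21355 against 15082) were higher. ATP5MC1 (2.16), PPP1R14C (1.98), ITPK1 (1.76), S100A9 (1.72), SERPINE2 (1.64), NPTX2, RASD1 (both 1.60) and TUBB2B (1.55) had the largest positive differences. In all, 61 genes were at least 2-fold higher and 69 lower, a balance that turned at 1.5-fold (370 and 347) and after background subtraction (542 and 380).

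In the 9-array limma fit 0 of 13237 genes passed for HIF1A knockdown, with 1433 at an unadjusted p under 0.05; HIF1A itself had an adjusted p of 0.134, and BNIP3, ALDOC and ATP5MC1 of 0.0861. In that fit 30 of 34 hypoxia-inducible genes and 21 of 23 glycolysis genes had HIF1A differences below 0, with medians of -0.61 and -0.39. The fit's 12 h control level also draws on the shNDRG3 arrays, those of 24 h included, so its values differ from direct ones. CA9 was at -2.11 in the fit and at -1.64 directly. Against the 12 h shGFP array alone, 27 of 33 and 19 of 22 measured members were below 0, with medians of -0.61 and -0.28. The HIF1A term rests on 1 array, so the spread of shHIF1A cells was not measured. Calls over a list alone are therefore not given for HIF1A, and their absence is no contrast with NDRG3. Without the 24 h arrays limma called 1074 genes higher and 937 lower, in the same fit with 1 residual degree of freedom and the prior of 26.27. On the shHIF1A array ERK pathway output genes had a median of -0.31 (0 percentile of random lists), with 15 of 19 members below 0 and 4 above. ETV5 was at -1.04 and ETV4 at -0.73. Stress response genes had a median of 0.24, or 0.13 among genes equal to 1 probe (92.5 percentile, inside the central 95%), and proliferation genes 0.18. Secreted factors (0.01), cholesterol biosynthesis (0.04), interferon-stimulated (0), oxidative phosphorylation (-0.08), hepatocyte (0.11) and other cell type genes (0.09) lay inside the central 95% of random lists; oxidative phosphorylation left it among genes equal to 1 probe (-0.13, 2.4 percentile).

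Genes induced by hypoxia were then followed as sets into arrays that had not defined them. The 280 genes at least 2-fold higher in shGFP cells at 12 h had a median of -0.36 in shNDRG3 against shGFP cells at 24 h (0 percentile of random sets), with 60 at least 2-fold lower. After background subtraction such a set held 645 genes with a median of -0.22 (0 percentile), 167 of them at least 2-fold lower and 30 higher. The 303 genes induced at 24 h had a median of 0.01 in shNDRG3 cells at 12 h (60.3 percentile), but the 102 genes induced at 6 h had 0.14 there (100 percentile), and the 284 induced at 12 h had 0.09 in shNDRG3 cells at 6 h (100 percentile). In shNDRG3 cells at 24 h the set induced at 6 h had a median of -0.39 (0 percentile, 99 genes). In shHIF1A cells at 12 h, the 307 genes induced at 24 h had a median of 0.01 (56.5 percentile), but the 102 induced at 6 h had -0.46 (0 percentile), with 15 at least 2-fold lower. Of the 313 genes 2-fold higher in hypoxia at 24 h, 99 were 2-fold higher at 12 h too. The 12 h medians of the 24 h set thus rest mostly on genes not 2-fold induced on those arrays. They cannot show whether either knockdown reduced induction. Likewise, 99 of the 284 genes induced at 12 h were 2-fold higher at 24 h. The -0.36 of that set at 24 h thus does not by itself show reduced induction either. For the 6 h set, 57 of 102 genes were 2-fold higher at 24 h. Between the 2 knockdowns at 12 h, the 6 h set was lower in shHIF1A than in shNDRG3 cells by a median of -0.52 (0 percentile, 25 genes 2-fold lower and 0 higher), and the 284 genes of the 12 h set by -0.38 (0 percentile, 38 lower and 2 higher). The 306 genes of the 24 h set had a median of 0.06 (99.9 percentile), though 24 of them were 2-fold lower and 4 higher. No replicates exist to test these differences.

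The last comparison set the knockdowns against each other across genes, which are not independent replicates. ATP5MC1 and ITPK1 were higher and TNNC1 and EMP1 lower on both the shNDRG3 arrays and the shHIF1A array. The other genes named as higher at each time in shNDRG3 cells were also higher there, such as GLO1 (11165 against 4811) and REEP1 (919 against 328). Those named as lower were lower there, such as TCIM (1605 against 4801) and, less so, IFI27 (912 against 1208) and GCNT3 (1927 against 2292). Within a platform these genes separated the shGFP arrays from those of the knockdown lines, apart from NDRG3 itself, REEP1 and GCNT3. REEP1 was at 638 on the 12 h shNDRG3 array and at 706 in shGFP normoxia. GCNT3 was at 1927 on the shHIF1A array and at 1743 in shGFP normoxia. The shNDRG3 difference at 6 h and the shHIF1A difference at 12 h, which share no array, had a Pearson r of 0.23 and a Spearman rho of 0.17 over 11874 genes. The 24 h shNDRG3 difference gave 0.24 and 0.19 over 12597 genes. At 12 h, where both used 1 shGFP array, r was 0.39, against 0.50 in simulations of unchanged groups with that array shared; the covariance was 0.0242 against 0.024. Of 8 genes 2-fold lower at 6 h in shNDRG3 cells, 4 were 2-fold lower in shHIF1A cells (0.046 for independent lists).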

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

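The tests of an equal knockdown effect over time and of other splits were chosen after their values had been seen. The glycolysis list and the hypoxia-inducible list stood out because their shNDRG3 differences took opposite directions by time: medians of 0.10 and 0.13 at 6 h (99.6 and 100 percentile of random lists) against -0.13 and -0.17 at 24 h (1.8 and 0.3 percentile). Among genes equal to 1 probe the 6 h medians were 0.10 and 0.08 (96.6 and 95.5 percentile), inside the central 95%. The difference between times was not tested, and the times lie on separate platforms.

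Many abundant transcripts were lower on the 24 h shNDRG3 array: 64 genes were at least 4-fold lower and 5 at least 4-fold higher. A knockdown effect equal over time is argued against, since NDRG3 itself was depleted at all times while the higher of the 6 h and 12 h medians of the 64 genes was -0.02. The authors' gene-level summary is argued against as the source, since 76.6% of probes past 2-fold were lower too. For a different mix of cell populations on that array no test was decisive: across 10949 genes its difference correlated with that between the shGFP normoxia arrays (Spearman rho 0.29, 0.29 given the level on those arrays), against 0.08 for shNDRG3 at 12 h and 0.30 for shHIF1A; this met the bound set in advance for a mix, but the normoxia arrays lie on different platforms, so their difference also holds platform and probe effects. A different mix, an NDRG3 effect that appears only by 24 h and culture conditions cannot be told apart with these arrays. The shHIF1A array had a rho (0.30) close to that of the 24 h shNDRG3 array (0.29). A different mix on the shHIF1A array therefore cannot be excluded either.

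Genes induced at 12 h were lower on the same array (median -0.36). Among sets matched on the difference of the normoxia arrays this stayed at the 0.0 percentile, below the bound set in advance against a different mix. That bound was wrong: the normoxia arrays lie on different platforms, so their difference also holds platform and probe effects and matching on it cannot exclude a mix; this condition was added after the value was seen. A different mix and a late effect of NDRG3 on the genes induced at 12 h therefore cannot be told apart. Of 284 genes induced at 12 h, 99 were 2-fold higher at 24 h too. Their lower median is thus not the same as reduced induction at 24 h.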

How the results depend on the processing

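The second quantile normalization, genes equal to 1 probe, background subtraction and the filter on each platform were chosen after seeing the data; the other alternatives were planned. No list or set median that lay outside the central range changed sign, and no correlation did, but the balance of higher and lower genes turned in some counts, given below. Centring on the array median, the second quantile normalization and the filter on each platform left all headline counts within 1.5 times. Where the alternative's own construction does not show it, the cause was not tested. With no filter, limma called 3 genes for hypoxia and 0 for NDRG3, and r between the knockdowns was 0.20 at 6 h; with the 60th percentile filter, hypoxia had 148 genes and r was 0.26 at 6 h and 0.26 at 24 h. With pseudocount 8, limma called 85 genes for hypoxia and 2 for NDRG3; with the higher pseudocount it called 7 and 0, and 6 genes were 2-fold apart for shNDRG3 at 6 h and 79 for shHIF1A. The probe tables gave 2 NDRG3 calls, a median of 0.03 for induced genes in shNDRG3 cells at 12 h (97.7 percentile), and r of 0.20 and 0.21. Genes equal to 1 probe, a smaller set, gave 353 for hypoxia at 24 h, 7, 12 and 235 for shNDRG3 at 6, 12 and 24 h, and 0 calls for NDRG3 knockdown in limma (733 at an unadjusted p under 0.05), NDRG3 itself not being in that set.

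Background subtraction raised dim-gene differences: 2-fold counts were 604, 1491 and 2351 for hypoxia, 409, 389 and 1977 for shNDRG3 and 922 for shHIF1A, limma called 0 genes for hypoxia (1953 at an unadjusted p under 0.05) and 0 for NDRG3 (805), and r was 0.14 and 0.18. The higher genes among them were 350, 770 and 1166 for hypoxia, 206, 181 and 882 for shNDRG3 and 542 for shHIF1A, so in shNDRG3 cells at 24 h the excess of lower genes (298 against 78) was smaller, at 1095 against 882, and the balance turned for hypoxia at 24 h (1185 lower), shNDRG3 at 6 h (203 lower) and shHIF1A (380 lower). At 1.5-fold the counts were 390, 1602 and 2114 for hypoxia, 96, 160 and 1443 for shNDRG3 and 717 for shHIF1A, and the balance turned for hypoxia at 12 h (799 higher, 803 lower) and 24 h (1044 and 1070) and for shHIF1A (370 and 347); at 3-fold they were 40, 103 and 112, then 2, 5 and 115, then 17. Moderation with trend and robust gave 123 genes for hypoxia and 4 for NDRG3. The set induced at 6 h had a median of 0.14 in shNDRG3 cells and -0.46 in shHIF1A cells at 12 h, against 0.01 and 0.01 for the 24 h set. Leaving out 1 time gave 90 to 949 genes for hypoxia, 0 to 646 for NDRG3 and 0 to 2011 for HIF1A; the highest came without the 6 h array for hypoxia and without the 24 h arrays for both knockdowns, with 1 residual degree of freedom there (prior 7.38 and 26.27). Among values of single genes and lists, 2074 stayed on their side, 88 lost and 76 gained a call or a place outside the central range, and 1 moved to it with the other sign. The mean over all probes was not run. No paired analysis was possible because each group held 1 array, beyond the limma fit that matches shNDRG3 to shGFP arrays by time. Signal over background limits dim genes.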

Other observations

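On the shHIF1A array at 12 h TUBB2B, a tubulin gene, was at 4250 against 1428 in its control, and NPTX2, a pentraxin gene, at 778 against 234. TUBB2B was also higher on the 24 h shNDRG3 array (12649 against 7795). On that array the transcription factor gene JUN was at 30758 against 10620 and CKB at 12021 against 2909, the creatine kinase gene also being higher at 6 h (6369 against 3820). JUN was named after its values were seen.

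The count of splits below was chosen after its value was seen. The knockdown effects of NDRG3 at 6 h and HIF1A at 12 h correlated across genes, with an r of 0.23 between effects that share no array. Given the 24 h shNDRG3 difference and the difference of the normoxia arrays, the partial r was 0.19 (bootstrap over genes 0.17 to 0.22). That range treats genes as independent and holds no variation between cultures. The partial r lay above the bound set in advance against a different mix of cell populations in the arrays. That bound was wrong: the normoxia arrays lie on different platforms, so their difference also holds platform and probe effects and the partial r cannot exclude a mix; this condition was added after the value was seen. A difference between the shGFP line and both knockdown lines that precedes hypoxia could also give this; no normoxia array of a knockdown line was analysed here, and it was not tested.

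For NDRG3 knockdown, limma called 1 gene in the real split of the 6 hypoxia arrays, and 3 of the 10 splits called at least as many. The highest other split called 1568 genes. With 10 splits the share is never under 0.05. Of the splits with 1568 genes there are 2, which put both 6 h arrays in one group and both 12 h arrays in the other; given the means per time, both are the same contrast of the cell lines at 24 h with its sign turned. They point to a structure of the samples, the difference between the 24 h arrays, and are no measure of chance for an effect over 3 times.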
